A study of Mus musculus with 18 samples.

How the data were processed

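Gene expression was measured by polyA-selected, directional mRNA sequencing in RN2 cells, a mouse acute myeloid leukemia line driven by MLL-AF9 and mutant Nras. Cells carried 1 of 4 lentiviral constructs and were sorted on day 5 after transduction. Cells with intact BE or seBE received 1 nM rapamycin or vehicle for 24 h. The 18 libraries form 6 groups of 3. The labels call the 3 libraries of a group biological replicates, nothing further states that they came from separate cultures or transductions, and the p-values measure the spread between these samples.

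The deposited table holds raw read counts per gene in integers, made by the authors with featureCounts. Per the submitters' processing notes, reads were trimmed with fastp 1.0.1, aligned to mouse genome GRCm39 with STAR 2.7.1a, handled with SAMtools 1.9 and counted with featureCounts from Subread 2.0.3, and DESeq2 was used for differential expression. The annotation release, the strand setting of the count, the handling of multi-mapping reads and the DESeq2 version are not given in the sources used here. Without the strand setting, sense and antisense reads of overlapping genes cannot be told apart in these counts.

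The count table lists 56748 Ensembl gene IDs. Symbols came from a table of Ensembl IDs and names, which matched 52073 of them. The other 4675 IDs held 2.36% of all counts and kept their ID as a name. Library totals ran from 13835979 to 23284932 counts.

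Genes were filtered with edgeR's filterByExpr on the 6 groups, which left 14985 genes holding 99.93% of the counts, 14595 of them with a symbol. All 18 libraries entered 1 fit of 6 group means in R 4.3.3 with edgeR 4.0.16, using TMM scaling and robust quasi-likelihood F tests. The common dispersion was 0.0176, a biological coefficient of variation of 13.3%. Adjusted p-values follow Benjamini and Hochberg over all genes tested within a comparison, with a threshold of 0.05. A standard error (SE) of a log2 fold change is its size divided by the square root of F. Levels are mean CPM, counts that edgeR scaled to TMM-adjusted library sizes, with the SD over 3 libraries.

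Each of 9 comparisons was fixed before the data were examined. They set intact BE against nCas9, the catalytic mutant against nCas9, intact BE against the catalytic mutant, seBE against nCas9 and seBE against intact BE. In these, intact BE and seBE were under vehicle, while the titles of the nCas9 and catalytic mutant libraries name no vehicle. Further comparisons set rapamycin against vehicle in intact BE and in seBE, and seBE against intact BE under rapamycin. The last set the drug effect in seBE against the drug effect in intact BE.

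Gene lists, 30 in number, were written before the data were examined, and 14 of their symbols were matched through older symbols. The 26 lists with at least 5 tested members were tested with camera from limma 3.58.1, at a preset correlation of 0.01, on log2 CPM with a prior count of 2, with adjustment over the 26 lists. The same test with a correlation estimated from the residuals, and fry, which asks only whether members move one way on balance, were alternatives. Single members were also counted with p-values adjusted over the list alone.

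The genes named were fixed by rule before the data were examined. Named first were the 10 largest rises and 10 largest falls among genes past the threshold that had at least 5 CPM in the higher group and no overlap between the libraries of the groups, predicted and clone-named models aside. Second came up to 4 members past the threshold from each list past its test, and up to 2 from other lists, in order of adjusted p. Last, Apobec1, Fkbp1a, Mtor, Cdkn1a, Mdm2 and Ung were always reported. Genes named outside this rule are said to be chosen after their values were seen.

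The share of counts from mitochondrially encoded genes was compared between groups with 2-sided exact permutation tests, which cannot give a p under 0.1 with 3 libraries against 3.

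Alternatives fixed before the data were examined were DESeq2 1.42.0 with its own size factors, no filter, a filter of 1 CPM in 3 libraries, a fit of the compared libraries alone, a replicate block, and leaving out each library in turn. Added after the data were seen were removal of a trend of fold change on transcript length and GC content, the same with a replicate block, thinning of all libraries to equal depth, and removal of mitochondrial genes with the most abundant gene. Length and GC content came from GENCODE M21 transcripts on GRCm38, an older build than the authors used, and were found for 97.4% of tested genes. The trend was a spline with 4 degrees of freedom, fitted on genes with a log2 CPM of at least 3.

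The procedure was tested on simulated changes. For rapamycin in seBE it called 10% of genes changed by 1.25-fold, 50% at 1.5-fold, 72% at 2-fold and 74% at 4-fold. For intact BE against nCas9 the shares were 6%, 56%, 74% and 82%, and for the difference between drug effects 4%, 36%, 50% and 68%. With an added slope of 0.1 log2 per doubling of length, 64 of 14383 unchanged genes were called before and 1 of 14043 after trend removal.

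Every column of the table was used. Ribosomal protein genes share reads with processed pseudogenes, mitochondrial genes with nuclear copies, and Hist1h1a, Slfn3, Klra2 and Oas2 with close paralogs, so that their levels are less certain than those of other genes. Some single genes that the naming rule selects are not reported here.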

Results

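RN2 mouse leukemia cells expressed 1 of 4 constructs. These were nCas9, the Cas9 nickase on which base editors are built, intact BE, a base editor with an active evolved APOBEC1 deaminase, its catalytic mutant with an inactive deaminase, and seBE, a base editor controlled by a small molecule, here rapamycin. Rapamycin is also an inhibitor of the kinase complex mTORC1. The nCas9 and catalytic mutant groups had 3 libraries each, and intact BE and seBE had 3 under vehicle and 3 under rapamycin. Total counts per library were 17753901, 14789497 and 18590586 for intact BE under vehicle, 23284932, 20044158 and 20832208 under rapamycin, and 18512944, 15565680 and 20285241 for nCas9. They were 13835979, 18924153 and 14499265 for the catalytic mutant, 14590542, 16887264 and 20518353 for seBE under vehicle, and 20787927, 21844463 and 22490858 under rapamycin. The stated purpose was to look for mechanisms of base editor toxicity in gene expression.

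**Figure D1:**
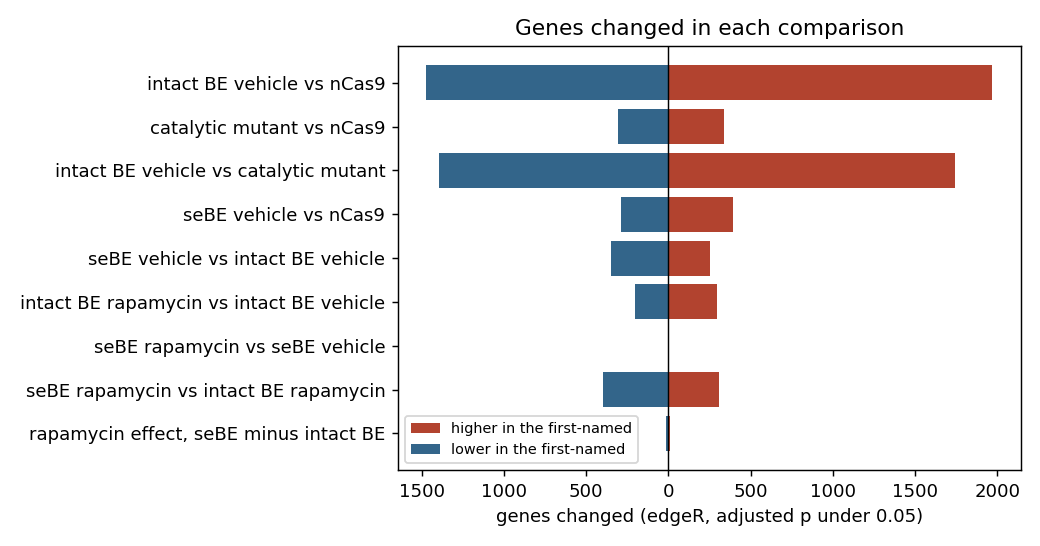
Bars give the number of genes past the threshold in each comparison, higher to the right and lower to the left, with 3 libraries per group. Intact BE against nCas9 had the most, 1969 higher and 1473 lower, and rapamycin in seBE had 0.

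Check genes for the drug target (Fkbp1a and Mtor), the response to DNA damage (Cdkn1a and Mdm2) and base excision repair (Ung) held close levels in all groups. Some other repair genes and p53 targets did change. Cdkn1a stood at 150 to 163 CPM and Mdm2 at 133 to 143 CPM across the 6 groups, Ung at 25 to 28.8 CPM, Fkbp1a at 191 to 211 CPM and Mtor at 61.1 to 73 CPM. None of these 5 genes passed the threshold in any of the 9 comparisons. For intact BE against nCas9 the log2 fold change was -0.06 ± 0.0795 (SE) for Cdkn1a, with adjusted p = 0.62, and 0.04 ± 0.0714 for Mdm2, with adjusted p = 0.754. Mouse Apobec1, the host gene related to the editor's deaminase, was lower in intact BE at 24.3 CPM than in nCas9 at 35.9 CPM (log2 -0.56 ± 0.132, adjusted p = 0.00178) and passed in no other comparison.

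Hoxa9, a target of MLL-AF9, ran from 266 to 313 CPM over the group means. Of 4 lists too short to test, megakaryocyte genes (2 measured members) peaked at 11.6 CPM for Itga2b and lymphocyte genes (4 members) at 0.775 CPM as a mean over libraries. Erythroid genes (2 members, Tfrc at 285 CPM) and fibroblast or endothelial genes (3 members, Pecam1 at 256 CPM) were led by genes that myeloid cells also express.

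Mitochondrially encoded genes took different shares of the counts. The share was 5.10% ± 0.586 (SD, n = 3) in nCas9, 4.53% ± 0.879 in the catalytic mutant, 3.19% ± 0.796 in seBE under vehicle, 3.58% ± 0.889 in seBE under rapamycin, 1.88% ± 0.127 in intact BE under vehicle and 2.11% ± 0.132 in intact BE under rapamycin. Intact BE under vehicle against nCas9, a ratio of 0.368, and seBE under vehicle against nCas9, a ratio of 0.625, each gave an exact permutation p of 0.1. So did intact BE against the catalytic mutant and seBE against intact BE in both arms. This p is the smallest the design allows. Rapamycin against vehicle gave an exact permutation p of 0.2 in intact BE and 0.5 in seBE, although the share was higher under the drug at each of the 3 replicate numbers in both editors. Ribosomal protein genes took 5.63% ± 0.226 in nCas9 and 4.40% ± 0.146 in intact BE under vehicle.

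**Figure D2:**
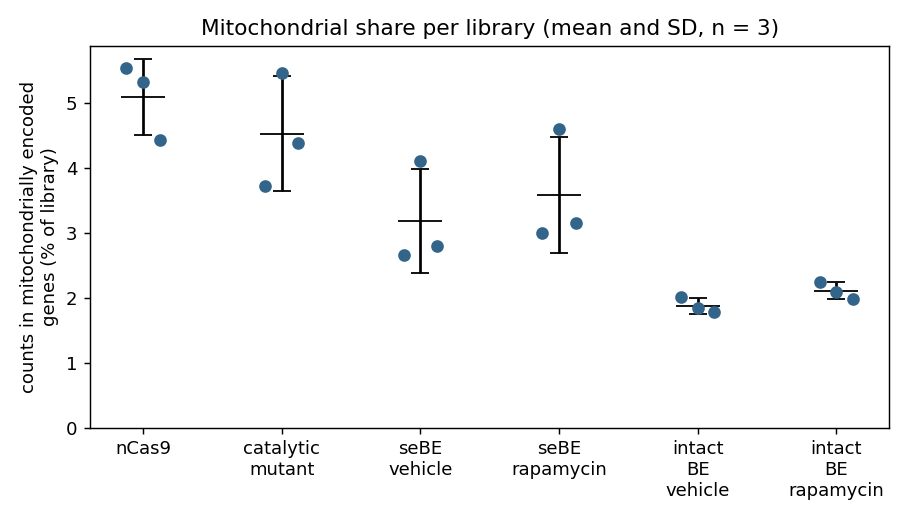
Points are single libraries, with the group mean as a bar and the SD, and the axis is the percent of library counts from mitochondrially encoded genes. The intact BE groups average 1.88% and 2.11% against 5.10% in nCas9.

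Fold changes also followed transcript length to a different degree in each group. The slope in log2 per doubling of length was 0.0599 ± 0.0267 (SD) in intact BE under vehicle, 0.0769 ± 0.0182 under rapamycin, -0.0734 ± 0.0234 in nCas9, -0.0487 ± 0.0237 in the catalytic mutant, -0.0222 ± 0.0266 in seBE under vehicle and 0.00738 ± 0.0269 under rapamycin. Ribosomal protein and oxidative phosphorylation transcripts are short, and their lists had medians or calls that moved when this trend was removed. Replicate 2 of nCas9 lay at 62.98 on the second principal component, where the other libraries lay between -24.5 and 21.5. In replicate 3 of the catalytic mutant the most abundant gene, ENSMUSG00000119584, which has no symbol in the table used here, held 0.153% of counts against 1.248% to 3.03% elsewhere. Malat1 stood at 313.7 CPM there against 1061 to 1819 CPM elsewhere.

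Intact BE under vehicle against nCas9 asks what the active editor changes beyond its nickase. Replication genes were higher with intact BE: Mcm4, a helicase subunit, stood at 322 ± 17.7 CPM against 198 ± 17.7 (log2 0.70 ± 0.0844, adjusted p = 1.06e-06), and the topoisomerase Top2a at 812 ± 41.0 against 569 ± 44.4 CPM (log2 0.51 ± 0.0805). Ribosomal protein genes were lower, with Rps20 at 932 ± 29.5 against 1434 ± 70.4 CPM, and mt-Nd1 was at 2472 ± 211 against 6541 ± 698 CPM. The stress gene Ddit3 was lower, at 12.7 against 31.8 CPM (log2 -1.32 ± 0.198), and so was the nuclear RNA Neat1 (log2 -1.66 ± 0.287). Of the largest rises, Cpox, a heme synthesis enzyme, had log2 1.05 ± 0.165 and Pou2f1, a transcription factor, 0.92 ± 0.0941 with adjusted p = 8.08e-08. Hist1h1a fell by 1.97 on the log2 scale. In all, 1969 genes were higher and 1473 lower, 284 of them by 2-fold or more, of which 246 were lower. The median size of a called change was 0.416, and 38% of tested genes had no overlap between groups, against 10% by chance.

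Synthesis and division lists were higher in intact BE than in nCas9. Of 30 mitosis genes 17 were higher and 0 lower, or 19 and 1 adjusted over the list alone (median log2 0.25, adjusted p = 2.94e-06, adjusted p = 0.232 with an estimated correlation), among them Top2a and Kif11 at 0.44. Of 30 S-phase genes 16 were higher and 2 lower, 17 and 3 adjusted over the list alone (median 0.22, adjusted p = 0.000904, adjusted p = 0.335 with an estimated correlation), with Mcm2 at 0.52 and Rrm1 at 0.49. Cholesterol synthesis genes had 10 of 24 higher and 1 lower by either count (median 0.13, adjusted p = 0.01, adjusted p = 0.446 with an estimated correlation), led by Idi1 at 0.79 ± 0.101. Fatty acid synthesis had 6 of 13 higher by either count (median 0.17, adjusted p = 0.0236, adjusted p = 0.329 with an estimated correlation), with Fasn at 0.51 and Acly at 0.46. MYC targets had 7 of 24 higher and 2 lower, 10 and 3 adjusted over the list alone (median 0.12, adjusted p = 0.0386, adjusted p = 0.335 with an estimated correlation), including Cad at 0.64 and Ddx21 at 0.65. MLL-AF9 program genes had 8 of 22 higher and 1 lower by either count (median 0.13, adjusted p = 0.0206, adjusted p = 0.223 with an estimated correlation), with Kit at 0.51 and Mef2c at 0.37. That call ended once the length and GC trend was removed, with adjusted p = 0.375. Fatty acid synthesis lost its call without intact BE replicate 2 (adjusted p = 0.0624), and MYC targets lost theirs without nCas9 replicate 2 (0.0805) or intact BE replicate 3 (0.081). After trend removal the fatty acid median was 0.11 and 14 MYC targets were higher.

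Protein folding genes were higher as well. Heat shock genes had 7 of 12 higher and 0 lower by either count (median 0.40, adjusted p = 0.000119, adjusted p = 0.223 with an estimated correlation), with Hsph1 at 0.51 and Hsp90aa1 at 0.40. ER chaperone genes had 12 of 20 higher and 0 lower by either count (median 0.24, adjusted p = 0.000443, adjusted p = 0.223 with an estimated correlation), with Hyou1 at 0.53 and Hsp90b1 at 0.43. ATF4 targets, which serve amino acid supply, went the other way: 10 of 32 were lower and 2 higher, 12 and 2 adjusted over the list alone (median -0.22, adjusted p = 0.000904, adjusted p = 0.347 with an estimated correlation). Slc1a5 was at -0.76 ± 0.0948 and Pck2 at -0.73, while Slc7a1 was at 0.51. After trend removal the median was -0.12 for ATF4 targets and 0.26 for heat shock genes.

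Translation and respiration lists were lower in intact BE. Ribosomal protein genes had 36 of 43 lower and 0 higher, 39 adjusted over the list alone (median -0.39, adjusted p = 1.87e-20, adjusted p = 0.223 with an estimated correlation), with Rps20 at -0.62 ± 0.0803 and Rps12 at -0.57. The median was -0.19 once the length and GC trend was removed. Mitochondrially encoded genes had 10 of 13 lower, 11 adjusted over the list alone (median -1.47, adjusted p = 1.87e-12, adjusted p = 0.223 with an estimated correlation), with mt-Nd1 at -1.40 ± 0.193 and mt-Nd6 at -1.58. Of the 10, mt-Co2, mt-Co3 and mt-Atp6 had a mean log2 CPM of only 2.75, 2.15 and 2.12, against 12.12 for mt-Nd1. The cause of these low levels was not tested, and how multi-mapping reads were counted is not given here. Nuclear oxidative phosphorylation genes had 12 of 26 lower and 3 higher, 13 and 4 adjusted over the list alone (adjusted p = 0.0196, adjusted p = 0.329 with an estimated correlation), with Ndufa2 at -0.64 and Cox4i1 at -0.42. This call ended at adjusted p = 0.899 without the length and GC trend. Interferon-stimulated genes had 5 of 27 lower, 4 adjusted over the list alone (median -0.52, adjusted p = 0.0196, adjusted p = 0.223 with an estimated correlation), with Stat2 at -0.69 ± 0.134 and Oas2 at -1.65 ± 0.355. Without nCas9 replicate 2 the interferon list was at adjusted p = 0.0939, and Cox4i1 was at 0.69 without the trend.

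DNA repair and p53 lists did not pass as lists. Base excision repair had 5 of 22 genes higher and 3 lower, 6 and 4 adjusted over the list alone (adjusted p = 0.676, median -0.10 and mean 0.01), although Tdg at 0.64 and Parp1 at 0.48 were higher. Mismatch repair had 3 of 8 higher (adjusted p = 0.133), and homologous recombination and Fanconi genes 5 of 25 higher and 1 lower (median 0.03, adjusted p = 0.575). After trend removal mismatch repair had 1 higher and 1 lower, and Fanconi genes 0 higher and 1 lower with a median of -0.07. p53 targets had 3 of 33 higher and 4 lower, 1 and 4 adjusted over the list alone (adjusted p = 0.976, median 0.04 and mean -0.02), with Psrc1 at -0.72 and Apaf1 at 0.38, whose call ended without the length and GC trend (adjusted p = 0.0797). The other lists that did not pass were NRF2 targets (4 of 16 higher, 1 lower, adjusted p = 0.133, but passing upward at 0.0386 with 7 higher and 2 lower after trend removal), glycolysis (7 of 25 and 4, adjusted p = 0.274), mature myeloid genes (0 of 25 and 3, adjusted p = 0.274), NF-kB genes (1 of 17 and 5, adjusted p = 0.431), mast cell markers (0 of 5 and 1, adjusted p = 0.443), immediate-early genes (0 of 19 and 2, adjusted p = 0.575), RAS-MAPK output (2 of 13 and 2, adjusted p = 0.575), primary granule genes (2 of 13 and 0, adjusted p = 0.858, median -0.10 and mean 0.04, also passing upward at 0.0386 after trend removal) and lysosome genes (5 of 31 and 4, adjusted p = 0.925).

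The catalytic mutant against nCas9 asks what remains when the deaminase is inactive. Asns was lower with the mutant, at 98.4 ± 7.31 against 157 ± 15.9 CPM (log2 -0.68 ± 0.0883, adjusted p = 8.3e-05). So were Cth, at log2 -1.15 ± 0.228, and Atf4, at -0.34 ± 0.0695. The ion channel gene P2rx3 was lower at 17.7 ± 2.76 against 43.2 ± 11.8 CPM, and the stress genes Nupr1 and Trib3 were at -1.27 and -1.11. Single genes that were higher included Mybbp1a at 0.46 ± 0.0728, Srm at 0.50 and Cad at 0.51. Rnf144b was higher at 1.14 ± 0.314 and Smurf1 at 0.83 ± 0.172, 2 genes for ubiquitin ligases. In all, 335 genes were higher and 309 lower, 36 by 2-fold or more, with a median size of 0.382, and 21.3% of genes had no overlap. The myeloid genes Cebpe, at 0.62, and Ccr2, at -0.64, moved apart with the same adjusted p = 0.000134.

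ATF4 targets had 8 of 32 lower and 0 higher in the mutant, 12 and 1 adjusted over the list alone (median -0.23, adjusted p = 1.28e-05, adjusted p = 0.505 with an estimated correlation). Ribosomal protein genes had 11 of 43 lower, 17 adjusted over the list alone (median -0.14, adjusted p = 3.59e-07, adjusted p = 0.598 with an estimated correlation), with Rps27a at -0.46 and Rpl23 at -0.41, and a median of -0.08 after trend removal. MYC targets had 8 of 24 higher and 0 lower, 12 and 1 adjusted over the list alone (median 0.13, adjusted p = 0.00011, adjusted p = 0.392 with an estimated correlation). Cholesterol synthesis had 3 of 24 lower and 0 higher, 9 and 1 adjusted over the list alone (median -0.14, adjusted p = 0.0279, adjusted p = 0.598 with an estimated correlation), with Nsdhl at -0.45 and Hmgcs1 at -0.30. Interferon-stimulated genes had 0 of 27 past the threshold by either count, and a list median of -0.27 (adjusted p = 0.0476, adjusted p = 0.426 with an estimated correlation). Mitochondrially encoded genes did not pass, with a median of -0.14 and adjusted p = 0.22, nor did p53 targets, with Phlda3 at 0.70 and adjusted p = 0.726 for the list.

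The number of genes changed in the mutant depended on single libraries and on the processing. It was 122 without nCas9 replicate 2, 380 and 407 without mutant replicates 1 and 3, 408 without nCas9 replicate 1, 230 without the length and GC trend, 423 from the compared libraries alone and 1014 by DESeq2, and 3 lists passed without nCas9 replicate 1. Rps27l, a p53 target at -0.31 with adjusted p = 0.0133, turned to 0.034 without the trend and was at 0.102 without mutant replicate 3. The call of Phlda3 ended without any of 4 libraries (adjusted p = 0.0915 to 0.219), without the trend (0.254) and in the compared libraries alone (0.102). By fry 2 lists passed, while ATF4 targets were at adjusted p = 0.0588, interferon-stimulated genes at 0.0712, ribosomal protein genes at 0.0906 and cholesterol synthesis at 0.166. The interferon call ended without any of 4 libraries (adjusted p = 0.0865 to 0.221), and that of cholesterol synthesis without nCas9 replicate 1 (0.215) or mutant replicate 2 (0.0572). Without nCas9 replicate 2, Rnf144b was at adjusted p = 0.178, Trib3 at 0.162, Nupr1 at 0.139, and Cth and Smurf1 at 0.0545. Hmgcs1 was at 0.267 without mutant replicate 1, and Nsdhl at 0.133 without mutant replicate 3. Trend removal ended the calls of Hmgcs1 (0.162), Nsdhl (0.116) and Rnf144b (0.0555).

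Intact BE against the catalytic mutant asks what the active deaminase adds. Sterol and lipid genes were higher with the active enzyme: Idi1 stood at 167 ± 7.87 against 92.9 ± 11.6 CPM (log2 0.84 ± 0.102, adjusted p = 3.94e-06) and the desaturase gene Scd2 at 892 ± 73.2 CPM (log2 0.57 ± 0.0786). Kif11, a spindle motor, was at 0.51 ± 0.0834 and Mcm4 at 0.56. mt-Nd1 was lower, at 2472 against 6002 CPM (log2 -1.28 ± 0.192), and so was Apoe, at log2 -1.33 ± 0.223. The myeloid gene Ccr2 was at 0.67 and Cebpe at -0.52. In all, 1743 genes were higher and 1398 lower, and of the 145 that differed by 2-fold or more, 140 were lower. The median size was 0.398, and 37.8% of genes had no overlap.

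Cholesterol synthesis had 12 of 24 higher and 0 lower, 12 and 1 adjusted over the list alone (median 0.24, adjusted p = 2.56e-06, adjusted p = 0.263 with an estimated correlation), with Hmgcs1 at 0.64 and Stard4 at 0.60. Enzymes of fatty acid synthesis had 7 of 13 higher by either count (median 0.26, adjusted p = 0.00137, adjusted p = 0.263 with an estimated correlation). Mitosis genes had 16 of 30 higher, 18 adjusted over the list alone (median 0.24, adjusted p = 1.64e-06, adjusted p = 0.263 with an estimated correlation). S-phase genes had 12 of 30 higher and 3 lower, 15 and 3 adjusted over the list alone (median 0.17, adjusted p = 0.00374, adjusted p = 0.469 with an estimated correlation), with Pola1 at 0.58. Without the length and GC trend the medians were 0.14 for mitosis and 0.10 for S-phase genes. ER chaperones had 9 of 20 higher and 1 lower, 10 and 1 adjusted over the list alone (median 0.20, adjusted p = 0.00197, adjusted p = 0.263 with an estimated correlation), with Hsp90b1 at 0.41. Heat shock genes had 5 of 12 higher, 7 adjusted over the list alone (median 0.24, adjusted p = 0.0068, adjusted p = 0.326 with an estimated correlation), with Hsp90aa1 at 0.38.

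Mitochondrially encoded genes had 10 of 13 lower by either count (median -1.28, adjusted p = 2.8e-11, adjusted p = 0.263 with an estimated correlation). Genes for ribosomal proteins had 24 of 43 lower, 28 adjusted over the list alone (median -0.24, adjusted p = 2.05e-10, adjusted p = 0.326 with an estimated correlation), with Rps15 at -0.62 ± 0.0877 and Rpl8 at -0.42. Trend removal left a median of -0.10, with 16 lower and 2 higher. Homologous recombination and Fanconi genes had 8 of 25 higher and 1 lower, 9 and 2 adjusted over the list alone (median 0.17, adjusted p = 0.0378, adjusted p = 0.263 with an estimated correlation). Among them were Brip1 at 0.48 ± 0.098, Blm at 0.39 and Brca1 at 0.34, with Fanca at -0.40. That call ended without the length and GC trend, at adjusted p = 0.671, when 1574 genes in all were changed. The count was 1662 without intact BE replicate 1 and 2089 without mutant replicate 2. The Fanconi call also ended without intact BE replicate 3 (0.0768) or mutant replicate 3 (0.101). Trend removal ended the calls of Brip1 (0.199), Blm (0.108), Brca1 (0.3), Rps15 (0.475), Rpl8 (0.444) and Cebpe (0.479), and Fanca was at 0.088 without mutant replicate 2. ATF4 targets did not pass, with 4 of 32 higher and 3 lower (median -0.06, adjusted p = 0.99), but after trend removal they passed upward, with 7 higher and 3 lower (median 0.16, adjusted p = 0.0106). Glycolysis (adjusted p = 0.0249, upward) and mast cell markers (0.0449, downward) likewise passed after trend removal.

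seBE under vehicle against nCas9 asks what the switchable editor does without its drug. ATF4-linked genes were lower: Nupr1 was at log2 -1.94 ± 0.354, Trib3 at -1.43, Asns at -0.64 ± 0.088 and Pck2 at -0.63. The phospholipase-family gene Pld4 stood at 30.1 ± 2.66 against 71.8 ± 7.80 CPM (log2 -1.26 ± 0.12, adjusted p = 3.8e-08) and P2rx3 at 11.7 ± 3.74 against 43.2 ± 11.8 CPM (log2 -1.90 ± 0.239). The chaperone gene Hsph1 was higher at 0.56 ± 0.09, Hspa8 at 0.31, and Traf3ip1 at 1.07 ± 0.201. Lipid enzymes were lower, with Fads2 at -0.65 ± 0.0887 and Scd2 at -0.47 ± 0.0786. In all, 395 genes were higher and 289 lower, 39 by 2-fold or more, with a median size of 0.377 and no overlap in 22.5% of genes. The count was 122 without seBE replicate 1, 165 without nCas9 replicate 2, 217 without seBE replicate 3 and 328 without nCas9 replicate 1.

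ATF4 targets had 14 of 32 lower and 0 higher in seBE, 20 adjusted over the list alone (median -0.28, adjusted p = 1.13e-12, adjusted p = 0.116 with an estimated correlation). Cholesterol synthesis had 7 of 24 lower, 11 adjusted over the list alone (median -0.25, adjusted p = 8.11e-07, adjusted p = 0.184 with an estimated correlation), with Acat2 at -0.54 and Lss at -0.45. Fatty acid synthesis had 5 of 13 lower and 0 higher, 6 and 1 adjusted over the list alone (median -0.15, adjusted p = 0.000752, adjusted p = 0.156 with an estimated correlation). Mitochondrially encoded genes had 0 of 13 past the threshold, 9 lower adjusted over the list alone (median -0.72, adjusted p = 3.46e-09, adjusted p = 0.156 with an estimated correlation). Ribosomal protein genes had 8 of 43 lower, 19 adjusted over the list alone (median -0.13, or -0.08 after trend removal, adjusted p = 4.2e-09, adjusted p = 0.281 with an estimated correlation). Interferon-stimulated genes had 1 of 27 lower by either count, Oas2 at -1.25 ± 0.347 (median -0.20, adjusted p = 0.013, adjusted p = 0.156 with an estimated correlation).

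Heat shock genes had 4 of 12 higher, 9 adjusted over the list alone (median 0.29, adjusted p = 3.94e-07, adjusted p = 0.116 with an estimated correlation). MYC targets had 7 of 24 higher, 11 adjusted over the list alone (median 0.16, adjusted p = 3.44e-05, adjusted p = 0.116 with an estimated correlation), with Cad at 0.46 and Mybbp1a at 0.38. Mitosis genes had 3 of 30 higher, 7 adjusted over the list alone (median 0.10, adjusted p = 0.0111, adjusted p = 0.43 with an estimated correlation), with Kif20a and Plk1 both at 0.32. NRF2 targets, which serve redox balance, had 4 of 16 higher and 0 lower, 6 and 1 adjusted over the list alone (median 0.17, adjusted p = 0.0198, adjusted p = 0.235 with an estimated correlation), including Gsr and Pgd at 0.29 and Txnrd1 at 0.28. p53 targets (1 of 33 higher, adjusted p = 0.714) and base excision repair (3 of 22 higher, adjusted p = 0.148) did not pass. Without nCas9 replicate 1 mitosis genes and NRF2 targets were at adjusted p = 0.0835, and by fry mitosis genes were at 0.103. The interferon list was at 0.0874 without nCas9 replicate 2 and 0.0795 without seBE replicate 3. Without seBE replicate 1, Oas2 was at 0.213, Plk1 at 0.177, Txnrd1 at 0.148, Pgd at 0.118, Lss at 0.117 and Gsr at 0.0595. Without nCas9 replicate 2, Kif20a was at 0.104 and Hspa8 at 0.0601, and Trib3 was at 0.0686 without seBE replicate 3.

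seBE against intact BE under vehicle compares the switchable with the constitutive editor when no drug is given. The transcription factor Tcf4 was lower in seBE, at 160 ± 9.71 against 278 ± 1.06 CPM (log2 -0.79 ± 0.0766, adjusted p = 5.84e-08). Lipid genes were lower, with Scd2 at 541 ± 36.6 against 892 ± 73.2 CPM (log2 -0.72 ± 0.0788, adjusted p = 6.31e-07), Idi1 at log2 -0.73 ± 0.101 and Hmgcs1 at -0.60. mt-Nd1 was higher, at 4379 ± 1069 against 2472 ± 211 CPM (log2 0.83 ± 0.191, adjusted p = 0.0346), as was Apoe at 0.82. The largest falls included B3gnt5 at -1.09. In all, 251 genes were higher and 347 lower, 16 by 2-fold or more, with a median size of 0.373 and no overlap in 29.4% of genes.

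Cholesterol synthesis had 17 of 24 lower and 0 higher, 19 adjusted over the list alone (median -0.37, adjusted p = 5.33e-18), and kept its call with an estimated correlation at adjusted p = 0.0479. Fatty acid synthesis had 8 of 13 lower, 10 adjusted over the list alone (median -0.41, adjusted p = 1.72e-12), and kept its call at 0.0114, with Fads2 at -0.64 and Elovl6 at -0.59. Genes for ribosomal proteins had 15 of 43 higher, 32 adjusted over the list alone (median 0.23, adjusted p = 5.33e-18, adjusted p = 0.185 with an estimated correlation), with Rps15 at 0.47 and Rps19 at 0.35, and 6 higher after trend removal. Mitochondrially encoded genes had 1 of 13 higher, 9 adjusted over the list alone (median 0.76, adjusted p = 6.5e-09, adjusted p = 0.185 with an estimated correlation). ER chaperones had 3 of 20 lower and 0 higher, 10 and 1 adjusted over the list alone (median -0.21, adjusted p = 1.51e-05, adjusted p = 0.185 with an estimated correlation). Mitosis genes had 3 of 30 lower, 12 adjusted over the list alone (median -0.15, adjusted p = 1.51e-05, adjusted p = 0.302 with an estimated correlation), with Kif11 at -0.37 and Top2a at -0.34, and a median of -0.09 after trend removal. S-phase genes had 3 of 30 lower, 10 adjusted over the list alone (median -0.12, adjusted p = 0.000363, adjusted p = 0.345 with an estimated correlation), with Pola1 at -0.45. ATF4 targets had 3 of 32 lower and 1 higher, 5 and 2 adjusted over the list alone (adjusted p = 0.00604, adjusted p = 0.576 with an estimated correlation), with Slc7a1 at -0.38 and Slc1a5 at 0.36.

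The number of changed genes between seBE and intact BE, 598, moved with the libraries used. It was 52 without seBE replicate 2, 54 without intact BE replicate 1, 193 without intact BE replicate 2, 308 without seBE replicate 1 and 374 without intact BE replicate 3. It was 314 without the length and GC trend, 945 without a filter, 1837 from the compared libraries alone and 1094 by DESeq2. ATF4 targets lost their call by fry (adjusted p = 0.196) and without intact BE replicate 2 (0.198) or seBE replicate 3 (0.122), and S-phase genes by fry (0.0579). Without seBE replicate 2 many single genes no longer passed, among them mt-Nd1 (0.238), Apoe (0.28), Pola1 (0.192), Rps19 (0.183), Top2a (0.161), Kif11 (0.117), B3gnt5 (0.106), Slc1a5 (0.349) and Slc7a1 (0.0844). Without the length and GC trend Rps15 was at 0.787, Slc1a5 at 0.103, Apoe at 0.0789 and Top2a at 0.0648.

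Rapamycin against vehicle in intact BE asks what the drug does where it is no switch. Asns fell from 127 ± 13.4 to 65.4 ± 6.09 CPM (log2 -0.95 ± 0.0892, adjusted p = 8.36e-09). Phgdh fell from 213 to 126 CPM (log2 -0.76 ± 0.0807), Mthfd2 by 0.75 and Cth by 1.96 on the log2 scale. The early growth response genes Egr1 and Egr3 rose, Egr1 from 36.5 ± 2.25 to 96.6 ± 21.1 CPM (log2 1.41 ± 0.134, adjusted p = 5.74e-08) and Egr3 by 2.55 ± 0.328. The integrin gene Itgam was at 0.58 ± 0.0795 and the lysozyme gene Lyz2 at 0.57 ± 0.0842. Serpinb2 at 2.01 ± 0.402 and Cd200r3 at 1.35 ± 0.177 were among the largest rises, and Trib3 at -1.77, Chac1 at -1.75 ± 0.279, Bcat1 at -1.22 ± 0.156 and Ighm at -1.14 ± 0.151 among the largest falls. In all, 296 genes rose and 201 fell, 44 by 2-fold or more, with a median size of 0.423 and no overlap in 22.3% of genes. The count was 214 without rapamycin replicate 1, 223 and 224 without vehicle replicates 2 and 3, and 873 from the compared libraries alone.

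ATF4 targets had 22 of 32 members lower and 1 higher under rapamycin, 26 and 1 adjusted over the list alone (median -0.52, adjusted p = 2.42e-28), and kept the call with an estimated correlation at adjusted p = 0.00989. The member that rose was Slc7a11, the cystine transporter, at 0.97. Enzymes of fatty acid synthesis had 5 of 13 lower, 12 adjusted over the list alone (median -0.39, adjusted p = 3.16e-11), and kept the call at 0.00989, with Scd2 and Fads2 both at -0.60. ER chaperones had 8 of 20 lower, 12 adjusted over the list alone (median -0.23, adjusted p = 1.85e-08), and kept it at 0.0451, with Hspa5 at -0.35 ± 0.0702 and Sdf2l1 at -0.54. Mast cell markers had 2 of 5 higher by either count, Gata2 at 0.58 and Hdc at 0.44 (median 0.31, adjusted p = 0.00207), and kept it at 0.0451. Cholesterol synthesis had 6 of 24 lower, 15 adjusted over the list alone (median -0.25, adjusted p = 3.21e-11, adjusted p = 0.0726 with an estimated correlation), with Acat2 at -0.65 and Mvd at -0.62. Ribosomal protein genes had 16 of 43 higher, 29 adjusted over the list alone (median 0.21, adjusted p = 2.47e-20, adjusted p = 0.0851 with an estimated correlation), with Rpl4 from 2175 ± 32.1 to 2724 ± 60.1 CPM and Rpl5 at 0.34.

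Mature myeloid genes had 5 of 25 higher, 10 adjusted over the list alone (median 0.26, adjusted p = 9.25e-07, adjusted p = 0.0686 with an estimated correlation), with Cd14 at 0.60 and Itgam at 0.58. Immediate-early genes had 4 of 19 higher and 1 lower, 4 and 2 adjusted over the list alone (median 0.20, adjusted p = 0.000516, adjusted p = 0.0851 with an estimated correlation), with Klf6 at 0.71 and Jun at -1.09. RAS-MAPK output had 2 of 13 higher by either count, Dusp5 at 0.69 and Dusp6 at 0.36 (median 0.13, adjusted p = 0.0158, adjusted p = 0.0862 with an estimated correlation). S-phase genes had 2 of 30 lower, 9 adjusted over the list alone (median -0.16, adjusted p = 5.52e-07, adjusted p = 0.107 with an estimated correlation), Rrm2 at -0.34 and Rrm1 at -0.28. Glycolysis had 4 of 25 lower and 1 higher, 6 and 1 adjusted over the list alone (adjusted p = 0.000353, adjusted p = 0.112 with an estimated correlation), with Pfkp at -0.31 and Ankrd37 at 1.30. MYC targets had 2 of 24 lower by either count, Srm at -0.39 and Ldha at -0.24 (median -0.10, adjusted p = 0.000353, adjusted p = 0.0851 with an estimated correlation).

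The remaining lists past the test for rapamycin in intact BE had at most 1 member past the threshold over all genes. Heat shock genes had 0 of 12 past the threshold by either count and a median of -0.19 (adjusted p = 0.000516, adjusted p = 0.121 with an estimated correlation). Oxidative phosphorylation had 1 of 26 lower by either count, Atp5g1 at -0.36 (median -0.11, adjusted p = 0.00322, adjusted p = 0.121 with an estimated correlation). Homologous recombination and Fanconi genes had 1 of 25 lower, Brip1 at -0.34, and 2 adjusted over the list alone (median -0.08, adjusted p = 0.0145, adjusted p = 0.0851 with an estimated correlation). Mitosis genes had 0 of 30 past the threshold by either count and a median of -0.07 (adjusted p = 0.0145, adjusted p = 0.419 with an estimated correlation). Mitosis genes were at 0.169 by fry and 0.14 without rapamycin replicate 1, Fanconi genes at 0.0516 without rapamycin replicate 1, and RAS-MAPK output at 0.0511 without rapamycin replicate 3. Single calls ended for Jun (adjusted p = 0.241), Klf6 (0.0989) and Serpinb2 (0.0583) without vehicle replicate 3 and Mvd (0.0714) without vehicle replicate 2. Without rapamycin replicate 1, Dusp6 (0.194), Rrm1 (0.181), Ankrd37 (0.163), Atp5g1 (0.105) and Pfkp (0.0592) did not pass, nor did Brip1 (0.15) without rapamycin replicate 2 or Ldha (0.137) without rapamycin replicate 3.

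Rapamycin against vehicle in seBE asks what the drug changes where it controls the editor. The genes that responded in intact BE moved little: Asns was at log2 -0.15 ± 0.0883, Phgdh -0.28 ± 0.0801, Mthfd2 -0.13 ± 0.0804 and Cth -0.40 ± 0.231, all with adjusted p = 0.999. Egr1 was at 0.13 and Egr3 at 0.04. Of 14985 genes tested, edgeR called 0 and DESeq2 0, while 493 had an unadjusted p under 0.05 against 749 expected by chance, and 8.06% had no overlap against 10% by chance. Without seBE rapamycin replicate 1 the count was 1.

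Lists moved slightly in seBE under the drug. ATF4 targets had a median of -0.08 (adjusted p = 0.00036, adjusted p = 0.444 with an estimated correlation), with 1 of 32 members lower adjusted over the list alone, and the other lists past the test had 0 members by either count. Cholesterol synthesis had a median of -0.10 (adjusted p = 0.00117, adjusted p = 0.46 with an estimated correlation). Fatty acid synthesis had a median of -0.11 but a mean of 0.03, and its test pointed down (adjusted p = 0.0217, adjusted p = 0.444 with an estimated correlation). MYC targets at a median of -0.07, oxidative phosphorylation at -0.04 and NRF2 targets at -0.05 each had adjusted p = 0.0253, and adjusted p = 0.444 with an estimated correlation. Mitochondrially encoded genes pointed up (adjusted p = 0.0321, adjusted p = 0.573 with an estimated correlation). After removal of the length and GC trend 3 lists passed, cholesterol synthesis at 0.000616, fatty acid synthesis at 0.0138 and ATF4 targets at 0.0159. The other 4 did not, with mitochondrially encoded genes at 0.206, oxidative phosphorylation at 0.162, MYC targets at 0.0576 and NRF2 targets at 0.0555. By fry 0 lists passed (adjusted p = 0.328 to 0.59). The count of lists was 2 without seBE vehicle replicate 1 and 3 without seBE rapamycin replicate 2. Each of the 7 calls ended without at least 1 library. Without seBE rapamycin replicate 1 cholesterol and fatty acid synthesis were at adjusted p = 0.218, without replicate 2 mitochondrially encoded genes were at 0.951, MYC targets at 0.326, NRF2 targets at 0.194 and oxidative phosphorylation at 0.13, and without replicate 3 ATF4 targets were at 0.0933.

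**Figure D3:**
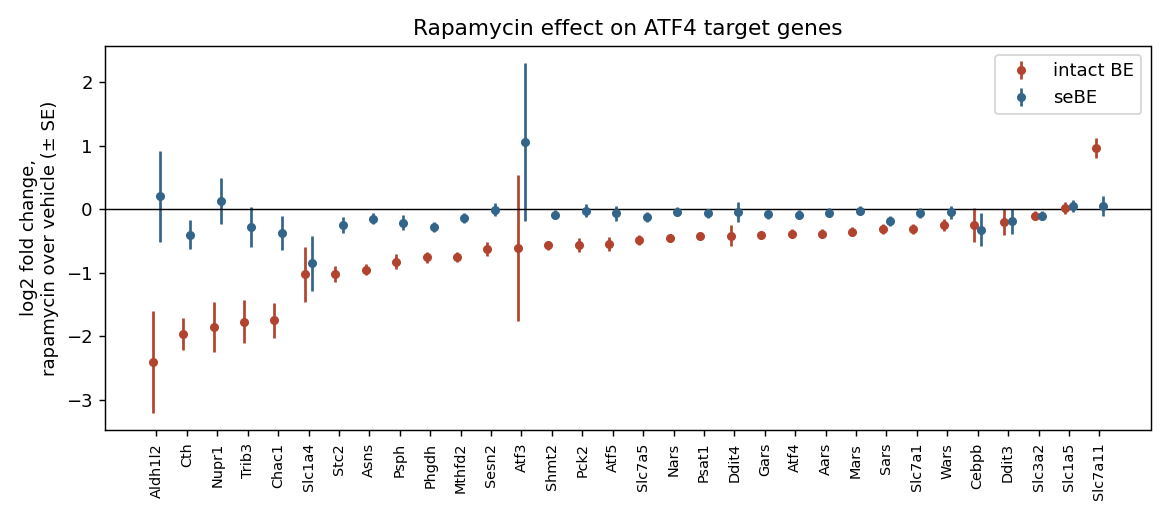
Points give the log2 fold change of rapamycin over vehicle with its SE for 32 ATF4 target genes, intact BE in red and seBE in blue, from 3 libraries per group. The list median is -0.52 in intact BE and -0.08 in seBE.

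seBE against intact BE under rapamycin compares both editors in the presence of the drug. Ighm was higher in seBE, at 38.7 against 14.8 CPM (log2 1.39 ± 0.149, adjusted p = 2.43e-07), as were the amino acid genes Cth at 1.26 ± 0.247, Pck2 at 0.64 ± 0.108 and Asns, at 90.9 ± 2.23 against 65.4 ± 6.09 CPM. Egr1 was lower, at 43.6 ± 9.86 against 96.6 ± 21.1 CPM (log2 -1.15 ± 0.131), and Egr3 was at -1.96 ± 0.312. The transglutaminase gene Tgm2 was at -1.37 and Slc7a11 at -1.07 ± 0.154. The chemokine receptor gene Ccr2 was at -0.63 ± 0.089 and Cybb at -0.57. In all, 305 genes were higher and 398 lower, 50 by 2-fold or more, with a median size of 0.404 and no overlap in 19.6% of genes. The count was 256 and 353 without intact BE replicates 1 and 3, 277 and 1114 without seBE replicates 2 and 3, and 312 from the compared libraries alone.

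ATF4 targets had 15 of 32 higher and 1 lower in seBE under the drug, 21 and 1 adjusted over the list alone (median 0.38, adjusted p = 1.26e-11, adjusted p = 0.155 with an estimated correlation). Mitochondrially encoded genes had 2 of 13 higher, 9 adjusted over the list alone (median 0.77, adjusted p = 7.66e-08, adjusted p = 0.155 with an estimated correlation), mt-Nd1 at 0.85 and mt-Nd4 at 0.90. Cholesterol synthesis had 9 of 24 lower, 13 adjusted over the list alone (median -0.23, adjusted p = 4.49e-07, adjusted p = 0.155 with an estimated correlation), with Cyp51 at -0.39 and Idi1 at -0.44. Enzymes of fatty acid synthesis had 4 of 13 lower and 0 higher, 7 and 1 adjusted over the list alone (median -0.22, adjusted p = 0.0116, adjusted p = 0.193 with an estimated correlation), with Scd2 at -0.34. Immediate-early genes had 3 of 19 lower, 6 adjusted over the list alone (median -0.23, adjusted p = 0.0041, adjusted p = 0.155 with an estimated correlation). Mature myeloid genes had 7 of 25 lower and 0 higher, 8 and 1 adjusted over the list alone, with a median of -0.03, a mean of 0.06 and a test that pointed down (adjusted p = 0.0296, adjusted p = 0.323 with an estimated correlation). Mast cell markers had 2 of 5 lower and 0 higher, 3 and 1 adjusted over the list alone (median -0.39, adjusted p = 0.0385, adjusted p = 0.155 with an estimated correlation), Hdc at -0.42 and Gata2 at -0.45.

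Stress and growth lists also passed the test between the editors under rapamycin. p53 targets had 5 of 33 higher and 1 lower by either count (median 0.15, adjusted p = 0.045, adjusted p = 0.155 with an estimated correlation), with Sesn2 at 0.54, Phlda3 at 0.75 and Pmaip1 at -0.35. MYC targets had 2 of 24 higher, 5 adjusted over the list alone (median 0.09, adjusted p = 0.0124, adjusted p = 0.197 with an estimated correlation), Nop56 at 0.33 and Srm at 0.36. Lysosome and autophagy genes had 5 of 31 lower and 1 higher, 5 and 2 adjusted over the list alone (median -0.10, adjusted p = 0.0124, adjusted p = 0.155 with an estimated correlation), with Map1lc3b at -0.33 and Lamp2 at -0.35. Oxidative phosphorylation had 2 of 26 higher, 4 adjusted over the list alone (median 0.07, adjusted p = 0.0116, adjusted p = 0.199 with an estimated correlation), and this call ended at adjusted p = 0.435 without the length and GC trend. Removing the trend moved the medians to -0.13 for fatty acid synthesis, -0.36 for immediate-early genes, -0.14 for mature myeloid genes and 0.06 for MYC targets, and left p53 targets with 3 higher and 1 lower. Trend removal also ended the calls of Srm (0.13), Phlda3 (0.107) and mt-Nd4 (0.0557). Of the 11 lists past the test, 5 remained in number without intact BE replicate 2 and 4 without seBE replicate 3, while 18 passed after trend removal. Without seBE replicate 3 mature myeloid genes were at adjusted p = 0.345, p53 and MYC targets at 0.113, and immediate-early and oxidative phosphorylation genes at 0.0511. Without intact BE replicate 2 fatty acid synthesis was at 0.122 and lysosome genes at 0.0639, without seBE replicate 1 mast cell markers were at 0.0972, and by fry mature myeloid genes were at 0.0527. Single genes that lost their call were mt-Nd4 (0.194) and Map1lc3b (0.0768) without seBE replicate 2, Phlda3 (0.145) without seBE replicate 3, and Pmaip1 (0.113) and Idi1 (0.0544) without seBE replicate 1. Without intact BE replicate 3 mt-Nd1 (0.0981) and Lamp2 (0.083) did not pass, nor did Scd2 (0.084) without replicate 2 or Atp5g1 (0.0813) without replicate 1.

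The difference between the drug effects asks whether rapamycin acted differently in seBE and intact BE. The genes were those of the drug response in intact BE: Egr1 differed by -1.28 ± 0.188 (log2 effect 1.41 in intact BE and 0.13 in seBE, adjusted p = 0.00176), Asns by 0.80 ± 0.125 (-0.95 and -0.15, adjusted p = 0.00176), Egr3 by -2.51 ± 0.457 and Ighm by 1.18 ± 0.207. Cth was at 1.56 ± 0.337, Mthfd2 at 0.62 ± 0.114 and Shmt2 at 0.48 ± 0.103. The myeloid genes Itgam at -0.58 ± 0.112 and Gata2 at -0.62 ± 0.121 rose in intact BE and not in seBE. In all, 28 genes differed, 11 with a positive and 17 with a negative difference and 10 by 2-fold or more, with a median size of 0.761, and 1044 had an unadjusted p under 0.05. The count was 11 without intact BE rapamycin replicate 1, 13 and 15 without intact BE vehicle replicates 3 and 2, 17 without seBE vehicle replicate 1, and 56 without seBE rapamycin replicate 1. It was 66 without a filter, 74 without the length and GC trend and 71 by DESeq2.

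ATF4 targets had 5 of 32 members with a positive difference, 22 positive and 1 negative adjusted over the list alone (median 0.40, adjusted p = 1.69e-20), and kept the call with an estimated correlation at adjusted p = 0.0464. Homologous recombination and Fanconi genes had 0 of 25 past the threshold, 1 adjusted over the list alone (median 0.15, adjusted p = 0.000686), and kept it at 0.0464. Ribosomal protein genes had 0 of 43, 19 negative adjusted over the list alone (median -0.25, adjusted p = 5.36e-21, adjusted p = 0.125 with an estimated correlation). Fatty acid synthesis had 0 of 13, 5 positive adjusted over the list alone (median 0.19, adjusted p = 2.33e-06, adjusted p = 0.0531 with an estimated correlation), and cholesterol synthesis 0 of 24, 1 adjusted over the list alone (median 0.16, adjusted p = 0.000137, adjusted p = 0.261 with an estimated correlation). Mature myeloid genes had 1 of 25 negative, 5 adjusted over the list alone (median -0.12, adjusted p = 0.000277, adjusted p = 0.148 with an estimated correlation). Immediate-early genes had 2 of 19 negative by either count (median -0.30, adjusted p = 0.000686, adjusted p = 0.125 with an estimated correlation), and mast cell markers 1 of 5, 2 adjusted over the list alone (adjusted p = 0.0142, adjusted p = 0.104 with an estimated correlation). Trend removal moved the medians of Fanconi genes to 0.08 and of mature myeloid genes to -0.18.

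The remaining lists past this test had 0 members past the threshold over all genes and 0 adjusted over the list alone. S-phase genes had a median of 0.17 (adjusted p = 1.48e-06, adjusted p = 0.148 with an estimated correlation), ER chaperones 0.17 (adjusted p = 4.97e-05, adjusted p = 0.125 with an estimated correlation) and mitosis genes 0.11 (adjusted p = 0.000542, adjusted p = 0.289 with an estimated correlation). Heat shock genes had 0.13 (adjusted p = 0.0149, adjusted p = 0.307 with an estimated correlation), glycolysis 0.10 (adjusted p = 0.0199, adjusted p = 0.318 with an estimated correlation) and NF-kB genes -0.22 (adjusted p = 0.0144, adjusted p = 0.279 with an estimated correlation). By fry 6 lists passed, and 8 of the 14 did not: glycolysis, NF-kB and heat shock genes at adjusted p = 0.189, mitosis at 0.179, cholesterol synthesis at 0.16, mature myeloid genes at 0.0843, S-phase at 0.0612 and immediate-early genes at 0.06. Heat shock genes were at 0.0513 without the length and GC trend. Glycolysis was at adjusted p = 0.294 and mast cell markers at 0.0785 without seBE rapamycin replicate 1, and heat shock and NF-kB genes were at 0.184 without seBE rapamycin replicate 3. Without intact BE vehicle replicate 2, Shmt2 was at 0.184 and Cth at 0.18. Without intact BE rapamycin replicate 1, Itgam was at 0.0928, Egr3 at 0.0841 and Mthfd2 at 0.0573, and Gata2 was at 0.0719 without intact BE vehicle replicate 1. Egr1, Asns and Ighm passed whichever library was left out.

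Across genes, which are not independent replicates, the drug effects in the 2 editors correlated with Pearson's r = 0.011 and Spearman's rho = 0.111 over the tested genes. Over the 497 genes changed in intact BE, r was 0.378, 400 genes (80.5%) had the same sign in seBE, and the median ratio of the seBE to the intact BE effect was 0.171.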

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

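The test of the difference between drug effects, the leaving out of libraries and the test of unequal ribosomal RNA removal were planned. The splits of the libraries and the tests of the other explanations were chosen after their results were seen.

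The drug effect differed between seBE and intact BE for 28 genes by the test of the difference itself. Genes that rose in intact BE and moved less in seBE were Egr3 (difference in log2 effect -2.51), Egr1 (-1.28), Cd200r3 (-1.24), Serpinb10 (-1.13), Adam8 (-1.07), Tmem71 (-0.85), Plaur (-0.79), Nab2 (-0.72), Tec (-0.62), Gata2 (-0.62) and Itgam (-0.58). Genes that fell in intact BE and moved less in seBE were Cth (1.56), Ighm (1.18), Gpt2 (1.05), Cgnl1 (1.03), Bcat1 (1.01), Scpep1 (0.89), Asns (0.80), Chdh (0.73), Mthfd2 (0.62) and Shmt2 (0.48). Among the other 7 genes, named after their values were seen, were Anxa5, Igf1r, Nt5e, Alas1, Cox7a2l and Nars. Many of these calls ended on leaving out single libraries: for Gpt2, Bcat1 and Adam8 without any of 9 libraries (adjusted p up to 0.29, 0.171 and 0.174), for Cgnl1 without 8 (0.123), for Cth, Nab2 and Tmem71 without 7 (0.18, 0.113 and 0.0972), for Chdh and Shmt2 without 6 (0.0993 and 0.184) and for Tec and Cd200r3 without 5 (0.106 and 0.0816). Itgam and Gata2 lost theirs without 2 libraries, and Egr3 and Mthfd2 without 1, as given above.

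Of 100 draws of the drug labels within the editors, out of 200 distinct ones, 11 gave at least the 28 genes of the real labels, the real one included, with 350 as the highest other, and 8 gave at least the 14 lists, with 17 as the highest other. These shares are above 0.05 and do not exclude chance. Of the 10 other draws with as many genes, however, 9 kept the labels of intact BE and so its drug effect. They are not draws without a change, and gave 44 to 350 genes, all above the real 28. A weaker response of the same direction in seBE is not excluded. Of 80 draws that mixed the labels of both editors, 1 gave as many, with 264 genes. The cause of that draw's count was not tested.

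The first pattern is a rapamycin response called in intact BE and not in seBE. Lower power in seBE with the same response underneath is argued against by fry on the ATF4 list in the test of the difference (adjusted p = 0.00816), and 1 mislabelled seBE library by the highest count of changed genes in seBE on leaving out any library, 1. ATF4 targets already at the low level before the drug are argued against, since under the drug their median was 0.38 higher in seBE than in intact BE, although under vehicle it was -0.14. For cholesterol and fatty acid synthesis that explanation is consistent with the data, since the higher of both list medians under the drug was -0.22. Another drug response in cells with seBE, whose drug-binding parts could take up rapamycin, stays open and was not tested.

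The second pattern is the broad difference between intact BE and both control constructs. A length and GC trend as the whole cause is argued against by 3096 genes changed against nCas9 and 1574 against the mutant without it. It may account for part of both, since only 2356 of 3442 and 1060 of 3141 calls were kept. A few abundant transcripts taking different shares are argued against, since 96% was the lower of both shares of called and still tested genes that stayed called without mitochondrial genes and the most abundant gene. An effect of the active deaminase, and a difference between separately transduced populations, both stay open, since construct and population are the same grouping here.

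The third pattern is the lower level of mitochondrially encoded transcripts in intact BE. The length and GC trend is argued against by a list median of -1.21 against nCas9 once it was removed, and reads shared with nuclear copies by the 5 members with most counts, mt-Co1, mt-Cytb, mt-Nd1, mt-Nd5 and mt-Nd2, of which the least negative was -1.39. Unequal removal of ribosomal RNA, if the unnamed most abundant gene reflects it, cannot be told apart from these data. The correlation of its share with the mitochondrial share, as deviations from group means over 18 libraries, was r = 0.139 and rho = 0.164 with a permutation p of 0.835, and r = 0.36 without the 2 farthest libraries. A biological cause was not tested.

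For the comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real count of changed genes and the highest of the other splits were 3442 and 0 for intact BE against nCas9, 644 and 1 for the catalytic mutant against nCas9, 3141 and 0 for intact BE against the catalytic mutant, and 684 and 0 for seBE against nCas9. They were 598 and 1 for seBE against intact BE, 497 and 0 for rapamycin in intact BE, 0 and 6 for rapamycin in seBE, and 703 and 11 for seBE against intact BE under rapamycin. For lists they were, in the same order, 13 and 9, 5 and 10, 9 and 9, 10 and 10, 8 and 10, 16 and 10, 7 and 9, and 11 and 8.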

How the results depend on the processing

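Both trend removals, the thinning and the removal of mitochondrial genes with the most abundant gene were chosen after seeing the data. Over 567 pairs of a named gene and a comparison there were 5643 values under settings other than leaving out a library. Of these, 5370 kept direction and side of the threshold, 263 kept direction but no longer passed, 8 passed newly and 2 reversed. By setting, 551 of 553 stayed with DESeq2, 561 of 567 with median-of-ratios factors, 560 without a filter, 564 with a stricter filter, 547 after thinning, 520 from the compared libraries alone and 455 after trend removal. All 93 list calls stayed with median-of-ratios factors, 84 after trend removal, 69 by fry and 8 with an estimated correlation. The reversed values were Rps27l in the catalytic mutant against nCas9, at 0.034 after trend removal and 0.035 with a replicate block as well.

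Counts of changed genes moved by more than 1.5 times as follows, and the cause was not tested. For the catalytic mutant against nCas9, 644 became 230 after trend removal, 423 from the compared libraries alone, 1014 by DESeq2 and 985 with a replicate block. For intact BE against the catalytic mutant, 3141 became 1574 after trend removal, with 1060 genes shared, and 2073 with a replicate block as well. For seBE against nCas9, 684 became 1089 with a replicate block and 1266 with the block after trend removal. For seBE against intact BE, 598 became 314 after trend removal, 945 without a filter, 1094 by DESeq2, 1173 with a replicate block and 1837 from the compared libraries alone. Rapamycin in intact BE went from 497 to 873 from the compared libraries alone and 1035 with the block after trend removal. seBE against intact BE under rapamycin went from 703 to 312 from the compared libraries alone, 1085 with the block and 1233 with the block after trend removal. The difference between drug effects went from 28 to 66 without a filter, 71 by DESeq2, 74 after trend removal, 65 with the block and 178 with the block after trend removal. Correlations of deviations between libraries of the same replicate number lay between -0.069 and 0.059, which shows no strong pairing across genes. Several counts rose with the replicate block, such as 644 to 985 and 598 to 1173, so variation shared by replicate number is not excluded. The mitochondrial share also moved alike by number under the drug, from 2.66% to 2.99%, 4.10% to 4.61% and 2.80% to 3.15% in seBE replicates 1 to 3. In intact BE it went from 2.02% to 2.25%, 1.84% to 2.08% and 1.78% to 1.99%. Shared cultures of the vehicle and rapamycin libraries are therefore not excluded, and no paired test of this share was made.

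For intact BE against nCas9, 3442 stayed within that range, at 3563 by DESeq2, 3376 after thinning and 3096 after trend removal, with 2356 genes shared. With a slope on length alone the self-test called 64 unchanged genes, or 131 by DESeq2, and cannot size the false calls here.

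List counts with an estimated correlation were 2 for seBE against intact BE under vehicle and 4 for rapamycin in intact BE. This test gave 2 for the difference between drug effects and 0 for all others. This test allows for the correlation between members, which was estimated at -0.07 to 0.587 where the preset was 0.01. By fry, 2 lists passed for the catalytic mutant against nCas9, 0 for rapamycin in seBE and 6 for the difference. After trend removal 8 lists passed for the catalytic mutant against nCas9, 3 for rapamycin in seBE and 18 for seBE against intact BE under rapamycin. The correlation of the drug effects across genes, 0.011, was 0.08 with a stricter filter.

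Leaving out each library in turn, which leaves 2 in a group, gave from 2331 to 3474 genes for intact BE against nCas9, 122 to 748 for the catalytic mutant against nCas9, 1662 to 2989 for intact BE against the catalytic mutant, 122 to 907 for seBE against nCas9, 52 to 518 for seBE against intact BE, 214 to 398 for rapamycin in intact BE, 0 to 1 for rapamycin in seBE, 256 to 1114 for seBE against intact BE under rapamycin and 11 to 56 for the difference. Lists ran, in the same order, from 11 to 13, 3 to 7, 8 to 9, 9 to 12, 7 to 9, 15 to 16, 2 to 8, 4 to 15 and 12 to 15, and the correlation of drug effects from -0.004 to 0.052. The calls lost by named genes ran from 14 in 242 pairs without nCas9 replicate 3 to 70 in 173 without seBE vehicle replicate 1. Thinning to the smallest library ended 20 calls in 567 pairs, while changed genes rose to 671 for the catalytic mutant and 715 for seBE against nCas9. Whether depth limited the weakest genes was not tested.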

Other observations

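The tests of the genes shared by both arms and of the correlations along the deaminase axis were planned before their results were seen, while the splits of that axis, the leaving out of libraries and the genes named in this part were chosen after.

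Some genes set seBE apart from intact BE with and without the drug. Tcf4, a transcription factor of progenitor and dendritic cells, stood at 160 ± 9.71 CPM (SD, n = 3) in seBE under vehicle and 172 ± 1.02 under rapamycin. It stood at 278 ± 1.06 and 309 ± 5.42 CPM in intact BE, 266 ± 25.6 in nCas9 and 282 ± 31.2 in the catalytic mutant. The seBE to intact BE log2 fold change was -0.79 under vehicle and -0.84 under rapamycin for Tcf4, with adjusted p = 5.84e-08 and 9.06e-09. Single genes that were lower in seBE in both arms, not tested as a group, included Heg1 at -0.46 and -0.68, Ccr2 at -0.52 and -0.63, Cd28 at -0.58 and -0.50, Cybb at -0.51 and -0.57, and Kit at -0.33 and -0.46. The fixed list of mature myeloid genes, which holds Ccr2 and Cybb, did not pass under vehicle and had a median of 0.13 (adjusted p = 0.285). The growth factor gene Angpt1 was at -0.55 and -0.76, and at 52.6 ± 6.29 CPM in seBE under vehicle it was close to 50.9 ± 8.80 CPM in nCas9, while intact BE had 77.3 ± 5.17. Under vehicle the call of Kit ended without intact BE replicate 1 (adjusted p = 0.123) or seBE replicate 2 (0.17), as did that of Cybb (0.114 and 0.0587). Angpt1 lost its vehicle call without any of 3 libraries (0.053 to 0.097).

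Among the genes higher in seBE in both arms were 4 that host small nucleolar RNAs, which were not tested as a group: Snhg12 at 0.53 and 0.56, Snhg5 at 0.45 and 0.63, Zfas1 at 0.43 and 0.51, and Gas5 at 0.31 and 0.34. Here intact BE stood apart and seBE lay nearer the controls. Snhg12 was at 31.3 CPM in seBE under vehicle, 31.2 in nCas9, 31.9 in the catalytic mutant and 21.7 in intact BE, and Zfas1 at 64.3, 66.9, 63.1 and 47.9. Snhg5 was at 78.7, 88.6, 87.4 and 57.8, and Gas5 at 344, 409, 351 and 277. Their vehicle calls ended without any of 2 libraries for Snhg12 (adjusted p up to 0.219), 3 for Snhg5 (0.147), 3 for Zfas1 (0.168) and 5 for Gas5 (0.342). Under rapamycin 1 library ended the call of Snhg12 (0.0518) and any of 3 that of Gas5 (0.171). Sterol genes lower in both arms included Idi1 at -0.73 and -0.44, Cyp51 at -0.51 and -0.39, and Sqle at -0.42 and -0.38. In the same order of groups Idi1 was at 100, 96.4, 92.9 and 167 CPM, Cyp51 at 188, 221, 198 and 268, and Sqle at 130, 131, 130 and 174. The rapamycin call of Idi1 ended without seBE replicate 1 (0.0544) or 2 (0.051).

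The hypothesis of a lasting difference between both cell populations was weighed on these genes, in vehicle and rapamycin arms that share no library. Both arms contrast the same constructs, however, and shared cultures are not excluded, so the arms may not be independent. Overlap beyond that of independent arms could come from either and cannot show what carries the difference. In both arms 171 genes passed in the same direction, 70 higher and 101 lower in seBE, where 5.11 and 9.22 were expected if the arms were independent, and 2 genes passed in opposite directions. After removal of the length and GC trend the number was 95, with 2.78 and 5.38 expected. It was 27 without seBE vehicle replicate 2, 105 without replicate 1, and 29 and 74 without intact BE vehicle replicates 1 and 2. Under rapamycin it was 87, 69 and 278 without seBE replicates 1, 2 and 3, and 72 and 85 without intact BE replicates 1 and 3. Across genes, which are not independent replicates, the arms correlated with r = 0.146 and rho = 0.27. The data are consistent with a lasting difference, which the construct and the history of the cell population could each carry.

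A second hypothesis was that rapamycin moves seBE cells toward the state of the active deaminase. Across 9117 genes with a mean log2 CPM over 3 the drug effect in seBE correlated with intact BE against the catalytic mutant at r = 0.299 and with intact BE against nCas9 at 0.1, and across all tested genes at 0.065 and 0.025. After trend removal, over 9119 genes, the values were 0.043 and -0.039, and over all tested genes 0.036 and 0.022. This met the planned mark against the hypothesis, a correlation under 0.1 along either axis. The test cannot decide it, since the drug effect in seBE had 0 called genes. Another split of the seBE libraries reached an absolute r of 0.637 with intact BE against the catalytic mutant before trend removal. The length slope also differed between these groups, so trend removal may take out part of a shift.

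The last hypothesis was that seBE cells under vehicle carry part of that state. The difference of seBE from nCas9 correlated across genes with intact BE against the catalytic mutant, which shares no library with it, at r = 0.288 over the 9117 genes, and at 0.406 after trend removal. Over all tested genes the values were only 0.1 and 0.106. Another split of the same 6 libraries reached 0.494, and 10 splits are too few for a share under 0.05, so this hypothesis may hold or not and stays open.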
